A study of Drosophila melanogaster with 8 samples.

How the data were processed

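RNA was taken from pooled extracts of staged embryos (N = 100, per the labels' protocols) of 2 genotypes, zen[7] homozygous and zen[7]/TM3, ftz-lacZ heterozygous, at stage 5 and stage 6-7. Per the labels' protocols, homozygotes were recognised by PCR, from the absence of a lacZ band and the presence of a control band from Dtg, total RNA was treated with DNase, and libraries were sequenced on an Illumina HiSeq as 100 bp paired reads with 200 bp inserts. The series' design text names biological replicates, but the labels do not say how embryos were split between pools, so p-values measure the spread between these pools.

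The authors deposited 1 table per library with whole-number counts of reads per gene, not normalized. STAR and HTSeq were used, per the submitters' processing notes, with no versions named. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes cannot be assigned with certainty. Each table holds the same 17468 gene IDs and the HTSeq summary lines for reads assigned to no gene. These lines, which name no gene, were left out of library sizes and tests. They held 12.89% to 18.22% of each total: 0.87% to 1.43% in no feature, 3.4% to 3.72% ambiguous and 8.01% to 13.39% not uniquely aligned, with 0 in the lines for low quality and not aligned. Symbols and positions came from the Ensembl 115 annotation of BDGP6.54, by gene ID: 17188 IDs matched and 280 did not, and the latter enter tests by gene but not those by chromosome.

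Samples were grouped by genotype and stage from the labels, and the test designs, gene lists, rule for named genes and processing alternatives were fixed before the data were examined. Counts were scaled with TMM (factors 0.907 to 0.957 at stage 5 and 1.058 to 1.068 at stage 6-7), filtered with filterByExpr (minimum count 10), which left 9360 genes, and fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest), with 1 mean per group over all 8 libraries so that the groups share the estimate of the spread. Contrasts were the genotype difference at each stage, their average, their difference, and the stage difference in each genotype, called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the absolute log2 fold change over the square root of F. CPM values use TMM-scaled library sizes.

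Named genes were all members of the amnioserosa list. For each genotype comparison they were also the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM over the libraries compared and both homozygous libraries outside the range of both heterozygous libraries. The same criteria gave 6 per direction for the stage comparisons and the interaction, and the 5 smallest p-values where fewer than 5 passed. Up to 4 members with the smallest p were named per list. Of the 25 lists (242 symbols), each with 2 or more tested members was tested with camera (limma 3.58.1, preset correlation 0.01, repeated with an estimated one) and fry. Where positions allowed, calls on chromosome 3 were compared with the rest by Fisher's exact test.

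Alternatives were RLE size factors from edgeR in place of TMM, library totals alone, no low-count filter, at least 10 CPM in 2 libraries, DESeq2 1.42.0 and limma-voom. Further ones were a replicate term shared by all groups or within stage, the libraries of a stage alone and genes off chromosome 3 alone. The last were glmTreat against 1.5-fold and leaving out each library. For the correlation with the stage effect, values from separate replicate numbers and without each library were added after the first values were seen. Leaving a library out leaves 1 in its group, which is then assumed to vary like the other groups. The fit was tested on simulated data drawn from the means and library sizes of these libraries (9208 genes). At stage 6-7 it recovered 59.2%, 72%, 82% and 93.9% of genes changed 1.5-, 2-, 3- and 4-fold, and called 15 of 9010 unchanged genes. At stage 5, where no gene was changed, it called 1 of 9208. The counts were drawn independently, with a spread per gene that all groups shared and no shift of a whole library. Replicates of the real groups differed unequally, so these rates may not hold for them. Intervals of 95% on shares are exact and cover counting error only.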

Results

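RNA was sequenced from whole Drosophila melanogaster embryos that were homozygous for zen[7], or heterozygous for zen[7] over TM3, ftz-lacZ, a balancer of chromosome 3 that carries a lacZ transgene. The gene zen encodes a homeodomain factor of the dorsal ectoderm that is needed for the amnioserosa, an extraembryonic epithelium. Embryos were taken at stage 5 (cellular blastoderm) and stage 6-7 (gastrula), with 2 replicate libraries of pooled embryos per genotype and stage, 8 libraries in 4 groups. The comparisons ask which transcripts differ between the genotypes at each stage, whether these differences change between the stages, and what changes with stage in each genotype. Gene counts summed to 29669956 (homozygous stage 5 replicate 1) to 37770105 (heterozygous stage 5 replicate 2) per library, and 9360 genes had enough counts to be tested. Levels below are CPM (counts scaled to library size), as mean ± SD with n = 2 libraries per group, and genotype differences are homozygous over heterozygous.

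The first principal component held 76% of the variance and separated the stages, and the next held 8% and separated the genotypes at both stages. Log2 CPM of the replicates correlated at 0.991 to 0.995 across genes. Replicates differed by more than sampling noise in every group, by a chi-square per degree of freedom of 6.9 in homozygotes at stage 6-7, 14.57 and 39.19 in heterozygotes at stage 5 and stage 6-7, and 48.72 in homozygotes at stage 5. Homozygous stage 5 replicate 1 lay at -56.2 on the first component, and the other stage 5 libraries at -42.1 to -45.1. Heterozygous stage 6-7 replicate 1 lay at 38.9, and the other stage 6-7 libraries at 48.81 to 51.12.

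The RNA of zen itself (FBgn0004053, minus strand of arm 3R, 6752864 to 6754194 on BDGP6.54) was not lower in homozygotes. At stage 5 it stood at 144 ± 14.1 CPM in homozygotes and 109 ± 4.32 CPM in heterozygotes, a log2 difference of 0.40 (SE 0.137) that did not pass the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.234). Without the low-count filter this difference passed, with an adjusted p of 0.009. At stage 6-7 zen stood at 56.4 ± 3.64 CPM in homozygotes and 49.6 ± 12.2 CPM in heterozygotes (log2 0.19, adjusted p = 1). The level of zen RNA therefore does not check the genotype labels.

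Genes of the amnioserosa list were lower in homozygotes at both stages. Of its 14 members, 7 fell at stage 5 and 8 at stage 6-7, and none was called higher by edgeR at either. The zinc-finger gene peb (FBgn0003053, arm X) dropped from 46.9 ± 6.81 to 15.8 ± 1.16 CPM at stage 5 and from 117 ± 8.45 to 36.7 ± 6.80 CPM at stage 6-7, log2 changes of -1.57 and -1.67 (SE 0.143 and 0.137, adjusted p = 8.58e-05 and 8.88e-06). The homeobox gene C15 (FBgn0004863, arm 3R) had the deepest fall of the list at stage 5, from 4.13 ± 0.143 to 0.845 ± 0.277 CPM (log2 -2.31), and at stage 6-7, from 15.7 ± 3.66 to 1.59 ± 0.502 CPM (log2 -3.30). The LIM-homeodomain gene tup (log2 -1.30 and -2.06), the Friend-of-GATA gene ush (-1.60 and -1.06), Ance, an angiotensin-converting enzyme homologue (-0.74 and -1.22), and the T-box gene Doc2 (-0.91 and -0.90) fell at both stages.

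Other members passed at a single stage by edgeR, though each passed at the other stage under some alternatives given below. The GATA factor gene pnr fell at stage 5, from 28.5 ± 1.61 to 10.1 ± 4.02 CPM (adjusted p = 0.00341), and had a log2 difference of -0.60 at stage 6-7 (adjusted p = 0.21). Dtg had a log2 difference of -0.34 at stage 5 (adjusted p = 0.124) and fell at stage 6-7 (log2 -0.61, adjusted p = 0.00259). The TNF-family ligand gene egr stood at 83.8 ± 40.8 CPM in homozygotes and 183 ± 15.8 CPM in heterozygotes at stage 5 (adjusted p = 0.241), and fell from 93.0 ± 7.74 to 14.6 ± 0.700 CPM at stage 6-7 (log2 -2.67, SE 0.349, adjusted p = 0.0249). No member passed the test of a difference between stages by edgeR, where 7 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 1 and 0. Kr had log2 differences of -0.03 and 0.11, and neither it nor Doc1, Doc3 or zen2 was called by edgeR at either stage. DESeq2 called Doc1 and Doc3 at stage 5 (adjusted p = 0.0385 and 0.0141) and 11 members in all, limma-voom called 8, and at stage 6-7 these tools called 8 and 9.

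**Figure D1:**
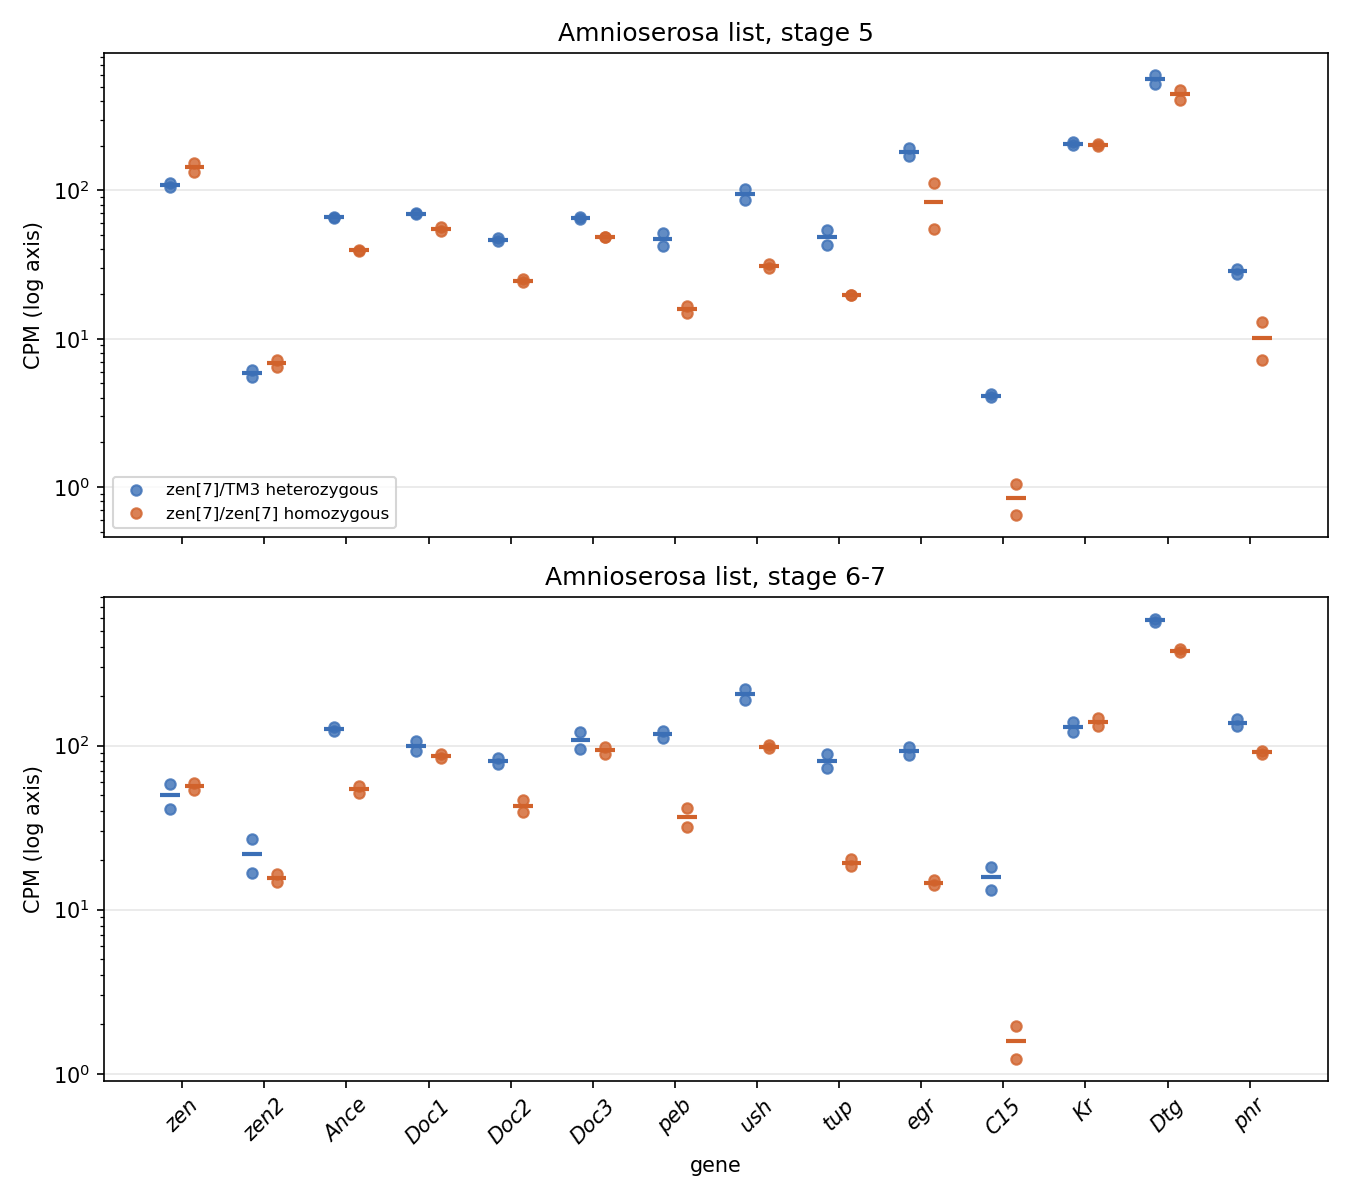
CPM (log axis) of the 14 genes of the amnioserosa list at stage 5 (top) and stage 6-7 (bottom), with a point for each of the 2 libraries of a group (blue heterozygous, orange homozygous) and a bar at their mean. Homozygous points of peb, tup, ush and C15 lie below the heterozygous points at both stages, and those of Kr overlap them.

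Adjusted over the list alone, 11 members fell and 1 (zen) rose at stage 5, and 10 fell and 0 rose at stage 6-7. The list stood lower than other genes by camera, a 2-sided test with a preset correlation, with a median log2 of -0.82 at stage 5 (adjusted p = 1.69e-09) and -0.76 at stage 6-7 (adjusted p = 1.28e-15). Neither call held with an estimated correlation (adjusted p = 0.818 and adjusted p = 0.456 with an estimated correlation). By fry, which asks whether the members move 1 way on balance, the adjusted p was 0.041 and 0.0201. Of the 6 members off chromosome 3, 4 fell at stage 5 and 5 at stage 6-7. The 1 that edgeR called at stage 6-7 alone was egr, which DESeq2 and limma-voom called lower at stage 5 too (adjusted p = 0.041 and 0.0156). Its call at stage 6-7 was lost without any 1 of the stage 6-7 libraries (adjusted p = 0.156 to 0.458), without the low-count filter (0.111), with a replicate block (0.121) or a block within stage (0.365), among genes off chromosome 3 alone (0.102) and against 1.5-fold (0.0709). Calls were gained by egr at stage 5 without homozygous stage 5 replicate 1 (adjusted p = 4.2e-06) or replicate 2 (0.00142), by pnr at stage 6-7 without the same libraries (0.000592 and 0.000406), by Dtg at stage 5 without replicate 1 (0.0296), and by Doc1 and Doc3 at stage 5 without replicate 2 (0.0484 and 0.0264). Doc3 at stage 5 also gained a call without heterozygous stage 6-7 replicate 1 or 2 (adjusted p = 0.0324 and 0.0337), and zen2 at stage 6-7 without heterozygous stage 6-7 replicate 1 (0.0173). Dtg was also called lower at stage 5 by DESeq2 (adjusted p = 0.0304), with the replicate block (0.0495) and with the block within stage (0.0292), and the blocks called Doc3 as well (0.0369 and 0.0125). At stage 6-7 pnr was called lower by limma-voom (adjusted p = 0.0381) and with the libraries of that stage alone (0.00319). Without the low-count filter Dtg, Doc1 and Doc3 passed at stage 5 (adjusted p = 0.0103, 0.0389 and 0.00246), and pnr and zen2 at stage 6-7 (6.65e-06 and 0.0498).

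At stage 5, 152 genes differed between the genotypes, 27 higher and 125 lower in homozygotes. Of the genes named by size, the largest rises were those of fok, from 7.11 ± 2.34 to 22.1 ± 2.96 CPM (log2 1.64, SE 0.214, adjusted p = 0.00166), and of the adenylyl cyclase gene Ac78C, from 91.5 ± 12.6 to 278 ± 22.3 CPM (log2 1.60, SE 0.105, adjusted p = 2.61e-06). Then came asRNA:CR44095, CG8066 (69.95 ± 5.86 to 195 ± 20.5 CPM), the nicotinic receptor subunit gene nAChRbeta2, DZIP1, CG13711, the muscle LIM protein gene Mlp84B, the kinetochore gene Mis12 and the odorant-binding protein gene Obp99a, with log2 changes from 1.58 down to 0.91. All of these 10 genes but fok lie on chromosome 3. The annotation places asRNA:CR44095 antisense to Cys, and with the strand setting of the counting not given in the sources used here, reads of the pair cannot be told apart.

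Of the genes named by size, the deepest falls at stage 5 were those of the receptor tyrosine kinase gene Alk, from 11.8 ± 1.93 to 3.17 ± 1.33 CPM (log2 -1.86, SE 0.235, adjusted p = 0.00156), of the leucyl aminopeptidase gene S-Lap1 (14.8 ± 0.688 to 4.14 ± 0.555 CPM, log2 -1.84) and of the methuselah-like receptor gene mthl8 (29.5 ± 1.74 to 8.45 ± 2.77 CPM, log2 -1.82). FBgn0029082, which has no symbol in the annotation used, fell by 1.80 on the log2 scale (adjusted p = 2.61e-06). The FGF ligand gene bnl (log2 -1.70), the cryptochrome gene cry (27.0 ± 1.06 to 8.72 ± 2.97 CPM, log2 -1.64), ush, peb, the GATA factor gene grn (log2 -1.53) and pnr followed. The gene cry overlaps lncRNA:CR46393 and, antisense, vib, and ush overlaps lncRNA:CR46258, so their reads can be shared.

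Unadjusted p-values under 0.05 numbered 1155 for the genotype effect at stage 5. The count of calls rose to 805 without homozygous stage 5 replicate 2 (141 of the 152 among them) and dropped to 66 and 67 without heterozygous stage 5 replicate 1 and replicate 2 (57 and 62 shared). Without homozygous stage 5 replicate 1 it was 149, with 101 shared. The calls of DZIP1, CG13711, Mis12 and Mlp84B were lost without heterozygous stage 5 replicate 2 (adjusted p = 0.0607, 0.0666, 0.0968 and 0.0582), and those of Obp99a and Mlp84B without replicate 1 (0.134 and 0.151).

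At stage 6-7, 166 genes differed, 49 higher and 117 lower in homozygotes. The gene mthl8 (FBgn0052475, arm 3L, 22428 to 26308) fell 19.3-fold, from 35.6 ± 0.691 to 1.85 ± 0.369 CPM (log2 -4.27, SE 0.21, adjusted p = 1.29e-07). The gene cry (FBgn0025680, arm 3R, 19212154 to 19215442) fell 15.3-fold, from 15.5 ± 0.268 to 1.01 ± 0.0193 CPM, and S-Lap1 (FBgn0035915, arm 3L) fell 14.7-fold, from 9.72 ± 1.42 to 0.657 ± 0.140 CPM, both with an adjusted p of 2.84e-07. Of the genes named by size, C15 was next, followed by Sarm, which encodes a TIR-domain protein (26.5 ± 2.50 to 3.47 ± 0.429 CPM, log2 -2.93). Then came Z600, an early inhibitor of the cell cycle (18.4 ± 3.68 to 2.44 ± 0.364 CPM, log2 -2.92, adjusted p = 0.00957). CG13653 (log2 -2.73), egr, the homeobox gene HGTX (log2 -2.42) and the fucosyltransferase gene FucTA (log2 -2.18) completed the 10 genes named. Z600 overlaps gdl, and FucTA lies antisense to Msh6.

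Of the genes named by size, the largest rise at stage 6-7 was that of FBgn0085799, which has no symbol in the annotation used, from 8.05 ± 0.972 to 19.96 ± 2.03 CPM (log2 1.31, SE 0.166, adjusted p = 0.000422). The hemolectin gene Hml rose from 3.34 ± 1.22 to 7.99 ± 0.299 CPM (adjusted p = 0.0342) and CG8066 from 83.5 ± 24.1 to 196 ± 5.79 CPM (adjusted p = 0.00194). CG2321, DZIP1, Obp99a, nAChRbeta2, tow, the glypican gene dlp and p53 rose by log2 1.18 to 1.03. All of these genes that the annotation places lie on chromosome 3. CG2321 lies antisense to Ptp99A and p53 to asRNA:CR46089.

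Unadjusted p-values under 0.05 numbered 706 at stage 6-7. The count of calls dropped to 105 without homozygous stage 6-7 replicate 1 (100 of the 166 among them), to 89 without its replicate 2 (88 shared) and to 105 without heterozygous stage 6-7 replicate 2 (96 shared). Of the stage 6-7 libraries, leaving out homozygous replicate 1 ended the calls of Hml and Z600 (adjusted p = 0.205 and 0.169), homozygous replicate 2 those of Hml, CG2321, p53 and Z600 (0.141, 0.109, 0.0781 and 0.14), heterozygous replicate 1 those of Hml, CG2321 and Z600 (0.24, 0.0556 and 0.0545), and heterozygous replicate 2 those of CG2321 and p53 (0.0876 and 0.131). The call of Hml was also lost without heterozygous stage 5 replicate 1 or 2 (adjusted p = 0.0574 and 0.0663), and that of CG8066 without homozygous stage 5 replicate 2 (0.0632). With library totals alone Hml did not pass (adjusted p = 0.0596), nor did Z600 without the low-count filter (0.0516).

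Calls were more frequent on chromosome 3, for which the genotypes differ along the whole chromosome. By their labels, homozygotes carry the zen[7] chromosome in both copies, and heterozygotes carry it beside TM3. A lacZ band alone does not tell heterozygotes from embryos with TM3 in both copies. Such embryos in the heterozygous pools would change the size of the genotype differences, and their share is not known. Of the called genes that the annotation places, 92 of 146 (63%) lay on chromosome 3 at stage 5 and 130 of 160 (81.2%) at stage 6-7, against 4045 of 9187 tested genes (44%). The odds ratio was 2.19 (95% interval 1.55 to 3.14, 2-sided Fisher's exact p = 4.46e-06) at stage 5 and 5.66 (3.77 to 8.74, exact p = 2.44e-22) at stage 6-7. Adjusted over the family of tests, these were 5.35e-06 and 3.66e-22. Within 1 Mb of zen, 4 of 117 tested genes were called at stage 5 and 1 at stage 6-7, beside 92 and 130 of the 4045 tested on the whole chromosome, and the 2 were not compared by a test.

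Direction differed between the chromosomes as well. On chromosome 3, 22 genes rose and 70 fell at stage 5, against 4 and 50 elsewhere (2-sided Fisher's exact p = 0.0133, adjusted p = 0.0133), and 47 rose and 83 fell at stage 6-7, against 0 and 30 elsewhere (exact p = 1.03e-05, adjusted p = 3.09e-05). Beside the count of 0 from edgeR at stage 6-7, 71 of the higher genes off chromosome 3 had an unadjusted p under 0.05. DESeq2 and limma-voom each called 2. At stage 5, beside the count of 4, these were 189, 7 and 5. Among the 200 genes of smallest p at stage 5, 27 rose and 92 fell on chromosome 3. Elsewhere 11 rose and 70 fell, and these directions were not compared by a test. Genes such as peb on X, tup, ush and Ance on 2L, and Alk on 2R were among the falls off chromosome 3.

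**Figure D2:**
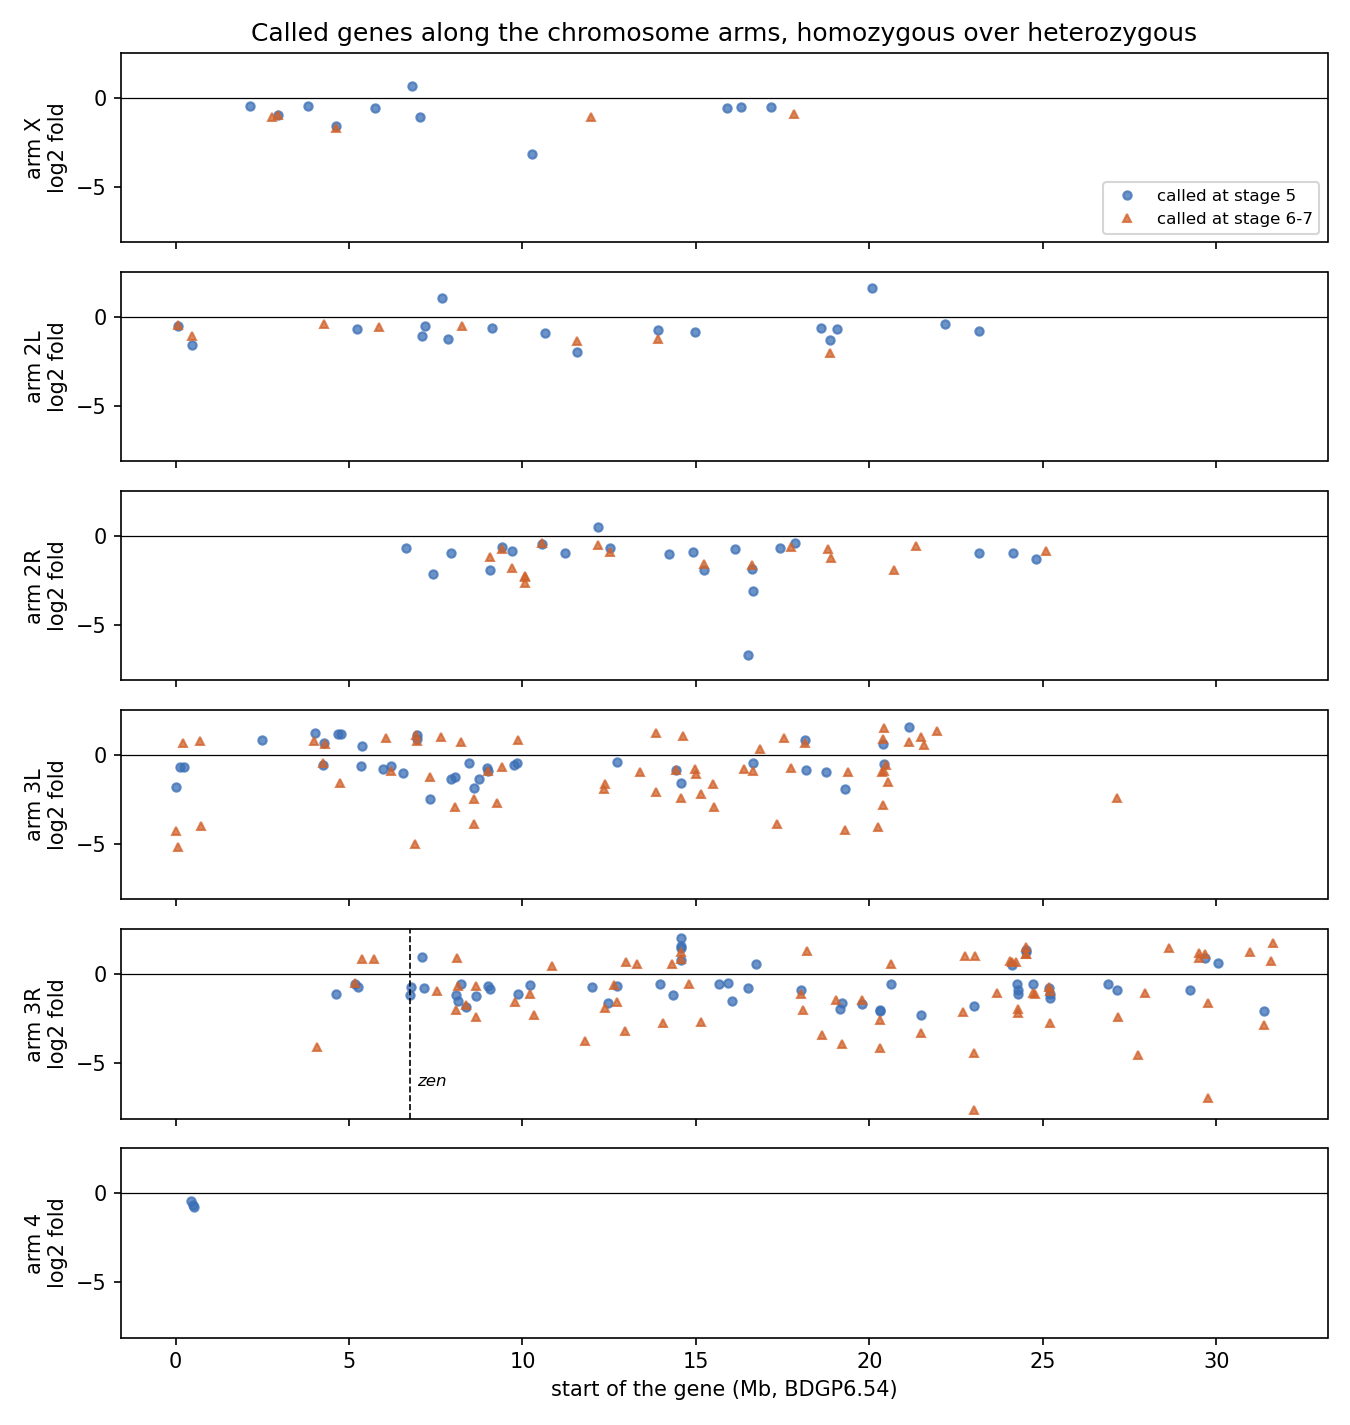
Log2 fold change (homozygous over heterozygous) of each called gene against the start of the gene (Mb, BDGP6.54) on arms X, 2L, 2R, 3L, 3R and 4, with circles for stage 5, triangles for stage 6-7 and a dashed line at zen. Arms 3L and 3R hold 92 of the 146 placed calls at stage 5 and 130 of 160 at stage 6-7, spread along both arms.

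Many genes were called in the same direction at both stages, which share no libraries. The calls are still not independent, since both stages share the fit's estimate of the spread per gene and the same chromosome 3 difference. The p-values below also treat genes as independent, so the numbers for independent lists are only a reference. In the higher direction 11 genes were shared, where independent lists of these sizes would share 0.14 (one-sided Fisher's exact p = 2.97e-19), and in the lower direction 51, against 1.56 (exact p = 5.33e-68). Ac78C, CG8066, nAChRbeta2, DZIP1, Mis12 and Obp99a rose at both stages, and mthl8, cry, S-Lap1, Sarm, CG13653, bnl, grn and HGTX fell at both. A single gene, CG8860 on arm 2R, was called in opposite directions, with a log2 change of 0.54 at stage 5 and -0.49 at stage 6-7. Among genes off chromosome 3, adjusted among themselves, 11 falls were shared (0.11 for independent lists), and 0 rises, since edgeR called 3 at stage 5 and 0 at stage 6-7. Across all tested genes, which are not independent replicates, the fold changes of the stages had a Spearman rho of 0.16. Without genes on chromosome 3 this rho was 0.064.

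With the stages averaged, 279 genes were called, 80 higher and 199 lower, and 211 of the 273 placed ones (77.3%) lay on chromosome 3. Of the amnioserosa list, 11 of 14 genes fell (camera adjusted p = 4.18e-14, adjusted p = 0.539 with an estimated correlation). Adjusted over the list alone, 11 fell and 1 rose. For the genotype effect averaged over stages the count of calls was 545 without homozygous stage 5 replicate 2 (254 of the 279 among them), 177 without heterozygous stage 5 replicate 2 (172 shared) and 174 without homozygous stage 6-7 replicate 1 (172 shared).

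**Figure D3:**
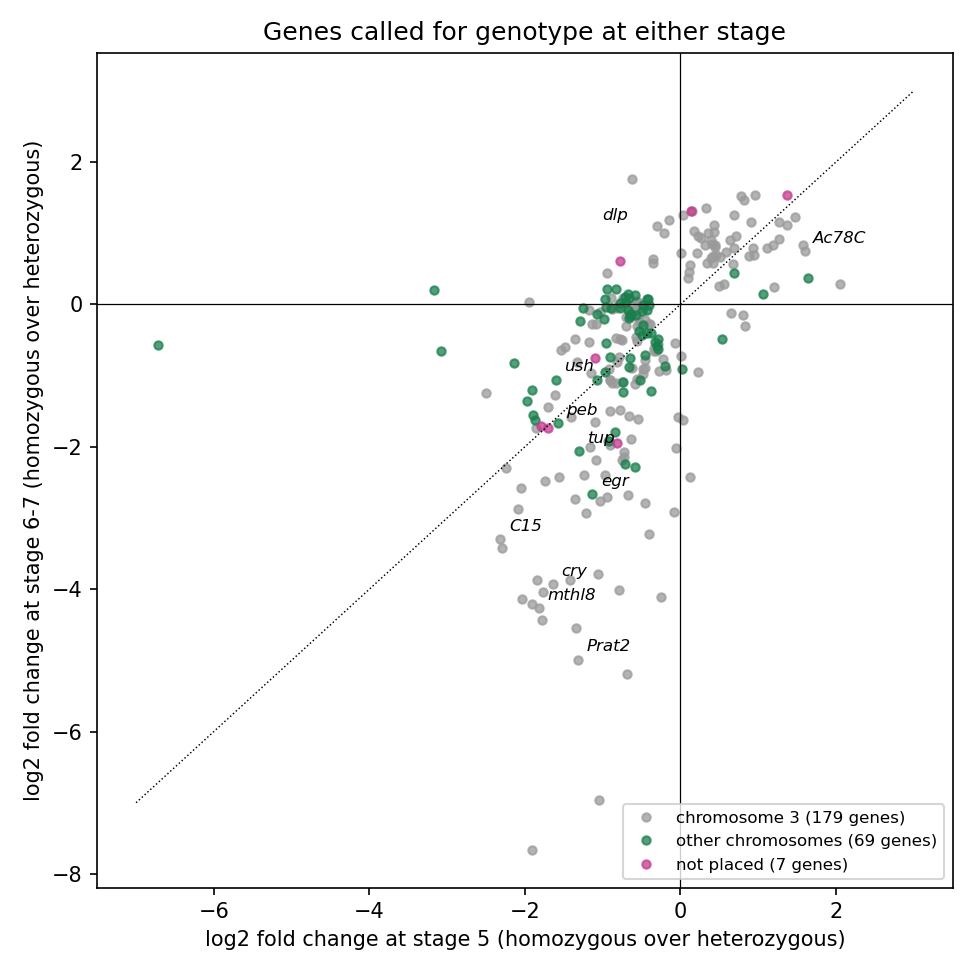
Log2 fold change (homozygous over heterozygous) at stage 6-7 against that at stage 5 for each gene called at either stage, coloured by chromosome (179 genes on chromosome 3, 69 on other chromosomes, 7 not placed), with a dotted line of equal change. The points of mthl8, cry and C15 lie below the line, with more negative values at stage 6-7, and that of dlp lies above it.

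By edgeR, the genotype difference itself differed between the stages for 7 genes. Of these, 1 had a higher and 6 a lower log2 change at stage 6-7 than at stage 5. Off chromosome 3, DESeq2 called 11 genes higher where edgeR and limma-voom called 0, and counts under other settings are given below. The fall of mthl8 was deeper at stage 6-7 by a log2 difference of -2.45 (SE 0.275, adjusted p = 0.00296), and so were those of cry (-2.29, adjusted p = 0.0055), S-Lap1 (-2.03, adjusted p = 0.0155) and Sarm (-1.72, adjusted p = 0.00296). The glypican gene dlp stood at 38.2 ± 0.628 CPM in homozygotes and 47.1 ± 5.46 CPM in heterozygotes at stage 5, and at 68.7 ± 5.88 and 31.9 ± 3.59 CPM at stage 6-7, a difference of 1.41 between the log2 changes (adjusted p = 0.00296). CG8860, overlapped antisense by asRNA:CR45264, stood at 22.3 ± 0.464 against 15.3 ± 0.0897 CPM at stage 5 and at 14.7 ± 0.756 against 20.6 ± 1.29 CPM at stage 6-7 (-1.02, adjusted p = 0.0239). The remaining gene, Prat2 of purine synthesis, stood at 3.23 CPM in heterozygotes and 0.098 CPM in homozygotes at stage 6-7, below the level for genes named by size, and was chosen after its values were seen (log2 -3.68, adjusted p = 0.0239). CG32473, gprs, smg, Usp1 and 5-HT2A, the next in the higher direction, did not pass (adjusted p = 0.0536 to 0.0686).

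In the genotype by stage interaction 629 genes had an unadjusted p under 0.05. The count of calls was 296 without homozygous stage 5 replicate 2 (241 of them higher, all 7 genes shared), 14 without its replicate 1 or without heterozygous stage 6-7 replicate 2 (6 shared in each), 3 without either heterozygous stage 5 library, and 4 without homozygous stage 6-7 replicate 2. The calls of cry, S-Lap1 and CG8860 were lost without heterozygous stage 5 replicate 1 (adjusted p = 0.0536, 0.0888 and 0.163) or replicate 2 (0.055, 0.0667 and 0.113), and those of S-Lap1 and CG8860 without homozygous stage 6-7 replicate 2 (0.147 and 0.147). CG8860 was also lost without homozygous stage 6-7 replicate 1 (adjusted p = 0.141) or heterozygous stage 6-7 replicate 2 (0.0555). With all libraries, limma-voom did not call cry, S-Lap1 or CG8860 (adjusted p = 0.0828, 0.106 and 0.0692), and CG8860 did not pass with library totals alone (0.0511). Calls were gained without homozygous stage 5 replicate 2 by all 5 genes that had not passed (adjusted p = 0.0051 to 0.0233), without replicate 1 by CG32473 (0.0165), and without heterozygous stage 6-7 replicate 2 by smg and Usp1 (0.0412 and 0.0243). All 5 also passed by DESeq2 (adjusted p = 0.000337 to 0.0089), with the replicate block (0.0099 to 0.0217), with the block within stage (0.000696 to 0.00385) and without the low-count filter (3.33e-06 to 0.000382).

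Among genes of Dpp signalling, the pathway of the dorsal ectoderm, 3 of 19 tested members were called at each stage. The tolloid-related protease gene tok fell from 150 ± 6.502 to 102 ± 1.27 CPM at stage 5 (log2 -0.56, adjusted p = 0.00367) and from 100.4 ± 3.95 to 48.5 ± 1.56 CPM at stage 6-7 (log2 -1.05, adjusted p = 8.88e-06). At stage 5 srw rose (log2 0.68, adjusted p = 0.0145) and the receptor gene tkv fell (log2 -0.70, adjusted p = 0.0205). At stage 6-7 tsg and cv-2, whose products bind Dpp-family ligands, fell (log2 -1.07 and -0.53, adjusted p = 0.00159 and 0.0312). Of the genes called at either stage, tok and srw lie on chromosome 3, and tkv, tsg and cv-2 lie elsewhere. With the stages averaged, srw and the protease gene tld rose (log2 0.62 and 0.31) and tok, tsg and cv-2 fell. Adjusted over the list alone, 3 rose and 6 fell at stage 5, and 2 rose and 3 fell at stage 6-7. The list did not pass as a set at either stage (camera adjusted p = 0.148 and 0.922).

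Of 14 tested maternal transcripts, 3 fell at stage 5. All 3 lie on chromosome 3 (smg on arm 3L, pum and bcd on 3R), for which the genotypes differ along the whole chromosome. Whether their RNA was loaded by the mothers or made by the embryos was not measured, so their position does not account for the falls. In heterozygotes smg stood at 88.7 CPM at stage 6-7, below its stage 5 level, and a difference in age between the pools stays open. The start of bcd (6755842) lies close to the end of zen (6754194). The translational repressor genes smg and pum stood at 139 ± 9.31 against 232 ± 27.4 CPM and at 107 ± 8.35 against 190 ± 22.96 CPM (adjusted p = 0.0017 and 0.00323), and the anterior determinant bcd at 2.90 ± 1.21 against 6.45 ± 0.436 CPM (adjusted p = 0.0481). The summed list stood at 768 and 861 CPM in the homozygous and 1046 and 953 CPM in the heterozygous stage 5 libraries. Adjusted over the list alone, 5 fell at stage 5 and 0 at stage 6-7, where edgeR, DESeq2 and limma-voom called 0 members and 0 had an unadjusted p under 0.05. The list did not pass as a set at either stage (camera adjusted p = 0.0706 and 0.753), but passed at stage 5 without heterozygous stage 5 replicate 2.

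Single members of 4 other lists fell at stage 5: the ventral furrow gene T48 (log2 -0.57, adjusted p = 0.0254), the Hox gene Dfd (-0.71, 0.0405), the cellularization gene nullo (-1.07, 0.0287) and the cell death gene hid (-0.82, 0.00647). Each was also the 1 member of its list to fall adjusted over the list alone at that stage. Of these 4 genes, nullo lies on X, and T48, Dfd and hid lie on chromosome 3. At stage 6-7, adjusted over the list alone, Z600 and term of the cellularization list and hid and Dronc of the cell death list fell, of which Z600 alone passed over all genes. No mesoderm, Hox or cell death gene was called by edgeR at stage 6-7, where 0, 1 and 3 had an unadjusted p under 0.05, DESeq2 called 0, 0 and 1, and limma-voom 0 of each. The mesoderm, Hox, cellularization and cell death lists did not pass as sets at stage 5 (camera adjusted p = 0.0654, 0.13, 0.876 and 0.192) or at stage 6-7 (0.533, 0.753, 0.0536 and 0.365). The mesoderm list passed at stage 5 without homozygous stage 5 replicate 2, and the cellularization list at stage 6-7 with the replicate block and without heterozygous stage 6-7 replicate 2.

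In 18 further lists with 208 tested memberships edgeR called 0 at either stage. At stage 5, 35 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 8 and 1; at stage 6-7 these were 15, 3 and 1. Ribosomal protein genes stood higher in homozygotes at stage 5 as a set, with a median log2 of 0.17 and 77 of 79 members positive (camera adjusted p = 1.92e-09). Their sum was 178700 CPM in homozygous replicate 1 and 144100 to 151600 CPM in the other stage 5 libraries, and the set did not pass without that replicate. Heat shock genes stood lower at stage 5 (median log2 -0.98, adjusted p = 0.00367), with sums of 761 and 633 CPM in homozygous and 870 and 929 CPM in heterozygous libraries, and did not pass without homozygous stage 5 replicate 2. Genes of the EGF receptor pathway stood lower at stage 5 (median log2 -0.26, adjusted p = 0.0231), and did not pass without homozygous or heterozygous stage 5 replicate 1. Each of these 3 sets had an adjusted p = 0.818 with an estimated correlation, and at stage 6-7 they had camera adjusted p-values of 0.753, 0.365 and 0.111. Among genes off chromosome 3 alone, the EGF receptor set did not pass at stage 5, and the ribosomal protein set did. The heat shock set was not tested there, since lists with fewer than 2 members off chromosome 3 were left out. At stage 6-7 the ribosomal protein and heat shock sets passed without heterozygous stage 6-7 replicate 1 and without its replicate 2, and the EGF receptor set without replicate 1. Directions of these passes are not given here. The homozygous ribosomal protein sums at stage 6-7, 140400 and 140000 CPM, lay between heterozygous replicate 1 (149300 CPM) and replicate 2 (127100 CPM). Leaving out 1 or the other moves the comparison of sums in opposite directions, so these passes do not repeat the stage 5 result.

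Adjusted over the list alone, aos, pnt and kek1 of the EGF receptor list fell at stage 5, and aos and kek1 at stage 6-7. With the stages averaged, these 3 genes passed over all genes (log2 -0.38, -0.43 and -1.13, adjusted p = 0.0163, 0.0435 and 0.0221), and the germ-band receptor gene Tollo rose (log2 0.86, adjusted p = 0.0382). At stage 5, D of the neurogenic ectoderm fell and sisA rose adjusted over the list alone, as did Ten-m (lower) and Tollo (higher) of the germ-band receptors. At stage 6-7, Tollo rose and hkb, of the gap and the endoderm lists, fell adjusted over the list alone. No other of the 18 lists had such a member at either stage. With the stages averaged and adjusted over the list alone, 5 EGF receptor pathway genes fell, 1 germ-band receptor gene rose and 1 fell, 2 ecdysone synthesis genes rose and 1 fell, and 1 gene each of the placode and endoderm lists fell.

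The lists for patterning had camera adjusted p-values of 0.506 and 0.781 (neurogenic ectoderm, stage 5 and stage 6-7), 0.726 and 0.365 (gap and terminal), 0.497 and 0.948 (pair-rule), 0.234 and 0.929 (segment polarity), 0.677 and 0.571 (Notch targets of the E(spl) complex), 0.497 and 0.929 (placode and tracheal) and 0.548 and 0.533 (germ-band receptors). Those for other cells were at 0.876 and 0.199 (pole cells), 0.579 and 0.0536 (endoderm, hemocytes and yolk nuclei), 0.148 and 0.437 (muscle), 0.712 and 0.781 (neural) and 0.631 and 0.533 (ovary). Sex determination genes had 0.148 and 0.781, and ecdysone synthesis genes 0.497 and 0.533. Of these, the neurogenic ectoderm and segment polarity lists passed at stage 5 without homozygous stage 5 replicate 2, the sex determination list without its replicate 1, and the muscle list among genes off chromosome 3 alone. At stage 6-7 the endoderm list passed with the replicate block, without homozygous stage 5 replicate 2 and without heterozygous stage 6-7 replicate 1, and the E(spl) list without heterozygous stage 6-7 replicate 2. Of the antimicrobial peptides AttB alone was tested, so no set test was made. Median, mean and test differed in sign for gap genes at stage 5 and for Dpp, pair-rule, placode and heat shock genes at stage 6-7, for mesoderm, germ-band receptor and neural genes in the average and for ovary genes in the difference between stages. In the difference between stages, mesoderm and heat shock genes were higher (camera adjusted p = 0.023 and 0.00112) and ribosomal protein genes lower (1.27e-05), each with an adjusted p = 0.822 with an estimated correlation.

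Between stage 5 and stage 6-7, 5142 genes changed in heterozygotes, 2660 higher and 2482 lower, and 5629 in homozygotes, 2911 higher and 2718 lower. The cellularization gene slam fell from 2074 ± 258 to 2.49 ± 0.571 CPM in heterozygotes (log2 -9.70, SE 0.256, adjusted p = 1.95e-09) and from 2021 ± 497 to 2.07 ± 0.354 CPM in homozygotes (log2 -9.92, adjusted p = 1.5e-09). CG15382 (antisense to aop), CG43725, Elba3 and bnk, another cellularization gene, fell by over 6 on the log2 scale in both genotypes, as did CG13711 in heterozygotes and Z600 in homozygotes. In heterozygotes CG32053, E(spl)m2-BFM, ttk, CrebA, Toll-6 and the segment polarity gene en rose by log2 3.45 to 2.78. In homozygotes E(spl)m2-BFM, en, Toll-6, the glypican gene dally, zfh1 (antisense to asRNA:CR45189) and FBgn0086901, which has no symbol in the annotation used, rose by log2 3.92 to 3.47.

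In heterozygotes all 10 tested E(spl) genes and 7 of 8 Hox genes rose, and 7 of 8 cellularization genes, 10 of 14 maternal transcripts and 8 of 11 gap and terminal genes fell (camera adjusted p = 0.000736, 0.00424, 0.000736, 0.00068 and 0.00158). Amnioserosa genes were higher as a set (10 rose, 3 fell, adjusted p = 0.0446) and heat shock genes lower (5 of 13 fell, adjusted p = 0.0446). In homozygotes the first 5 lists passed in the same directions (adjusted p = 0.00115, 0.00457, 0.00115, 0.00126 and 0.0017), with mesoderm and segment polarity genes higher (0.0459 and 0.0418) and ribosomal protein genes lower (35 fell and 2 rose of 79, adjusted p = 0.00126). None held with an estimated correlation, where the lowest was adjusted p = 0.541 with an estimated correlation in heterozygotes and 0.571 in homozygotes. Adjusted over the list alone, the counts of these lists in heterozygotes were the same. In homozygotes, adjusted over the list alone, 10 gap and terminal genes fell, 1 maternal transcript rose beside 11 that fell, and 0 ribosomal protein genes were called. Median, mean and test differed in sign for the placode and neural lists in heterozygotes and for the endoderm, neural, ovary and ecdysone lists in homozygotes. Scaling by library totals alone moved the stage effect in heterozygotes by 0.15 and the stage effect in homozygotes by 0.2 on the log2 scale, and 63.4% and 64.7% of calls were then higher (3352 of 5287 and 3638 of 5625), against 51.7% in each. With that scaling the medians of the ribosomal protein, placode and sex determination lists in heterozygotes, and of the heat shock, ovary and ecdysone lists in homozygotes, lost or changed their sign. The median of the ribosomal protein list in homozygotes moved from -0.23 to -0.03. Its sum was 178700 and 151600 CPM in the homozygous stage 5 libraries, replicate 1 standing apart, and 140400 and 140000 CPM at stage 6-7, and this fall was not tested without that replicate.

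Across the tested genes, which are not independent replicates, the genotype difference correlated with the stage effect averaged over the genotypes at a Spearman rho of -0.115 at stage 5 and 0.243 at stage 6-7. Both values come from the same libraries, so noise alone can give a rho other than 0. In a check chosen after these values were seen, the genotype difference came from 1 replicate number and the stage effect from the other, and rho was -0.212 and 0.099 at stage 5 and 0.329 and 0.04 at stage 6-7. Without 1 library it ran from -0.316 to 0.042 and from -0.026 to 0.272, so at both stages its sign depended on the libraries used. On leaving out 1 library, the sign changed only without homozygous stage 5 replicate 1 at stage 5 (0.042). At stage 6-7 it changed only without heterozygous stage 6-7 replicate 1 (-0.026). These are the libraries that stood apart from their stage on the first principal component.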

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

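Of the tests here, those of the odds on chromosome 3, of heterozygous embryos in the homozygous pools and of other splits of the libraries were chosen only after the result was seen, and that of the share of calls off chromosome 3 was limited only then to effects on the genes that carry a difference.

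A test of the difference between stages singled out 7 genes. The log2 genotype difference at stage 6-7 minus that at stage 5 was -2.45 for mthl8, -2.289 for cry, -2.029 for S-Lap1, -1.716 for Sarm, 1.407 for dlp, -1.025 for CG8860 and -3.677 for Prat2. Prat2 is near the floor, with 0.098 CPM in homozygotes and 3.23 CPM in heterozygotes at stage 6-7.

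The excess of genotype calls on chromosome 3 may come from sequence differences between the zen[7] chromosome and TM3, which the design confounds with zen along the whole chromosome. Differences that act on the genes carrying them are excluded as the whole cause of the calls, since 37% of placed calls at stage 5 (exact interval 29.2 to 45.4) and 18.8% at stage 6-7 (13 to 25.7) lay off chromosome 3, above a bound of 10%. For the calls on chromosome 3 they stay open, with odds ratios of 2.193 and 5.658, and effects in trans of such differences on genes of any chromosome were not separated from zen and stay open too. For a difference in age between the pools, a fold was predicted for each call from the stage effect. At stage 5, 0% of calls (upper bound 2.4%) had a prediction with the sign and at least 50% of the size observed. At stage 6-7 it was 0% (2.2%). The slopes came from uncalled genes and were shallow, -0.0373 at stage 5 and 0.067 at stage 6-7, which left little room to reach 50%. The shares therefore speak only against an effect of age with these slopes as the whole cause. Other differences in age between the pools were not tested and stay open for these calls. With the stages averaged, 1 of the 18 splits within stage gave as many called genes, the real one with 279, the highest other with 7, and the splits are too few for a share under 0.05.

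For the genes that differed between stages, sequence differences on chromosome 3 stay open, since 6 of the 7 lie there (exact binomial one-sided p = 0.0318). That number does not separate such differences from an effect of zen that changes with stage. The 2 cannot be told apart for these 6. The share rests on edgeR calls, and off chromosome 3 DESeq2 called 11 genes with a higher change at stage 6-7 where edgeR called 0. CG8860 lies on chromosome 2, where an effect in trans stays open. For a difference in age, 0 of 7 genes reached 50% of the observed size (cry: predicted -0.203, observed -2.289). The predicted values used the slopes of uncalled genes and ran only from -0.203 for cry to 0.015 for dlp. Other differences in age between the pools stay open. A change of the effect of zen with stage was not tested apart from these.

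Transcripts of the amnioserosa list stayed present in homozygotes, with a median share of the heterozygous level (ratio of group means) of 56.5% at stage 5 and 59.4% at stage 6-7, for which heterozygous embryos in the homozygous pools could be a cause. Such embryos would set a lowest share for all genes. Called falls outside the list with 5 CPM or more in heterozygotes were compared as highest homozygous over lowest heterozygous library. That ratio is never below that of the means. It lay below those medians for 20 of 98 falls at stage 5 and 38 of 69 at stage 6-7. This excludes such embryos as the whole cause of the medians, but not of the share of every member. At stage 5 C15 of the list had a ratio of 25.8%, below FBgn0029082 (30.9%), the lowest of the genes outside it. With 48 and 80 called falls beyond 2-fold, the outcome could be foreseen once the bound stood at the medians. By that ratio, shares were 6% for mthl8, 6.7% for cry and 8.7% for S-Lap1 at stage 6-7, and 31.6% for S-Lap1 at stage 5. The bound was changed after a first result was seen: with an earlier, lower bound, the stage 5 values would not have excluded this explanation, and a smaller share of heterozygous embryos stays open at both stages. Expression of these genes that does not depend on zen also stays open and was not tested.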

How the results depend on the processing

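The rho from separate replicate numbers, and the rho and the interaction of falls without 1 library, were chosen only after the result was seen. In the genotype comparisons and their difference, no named gene called in the edgeR fit or under the alternative reversed its direction. A change of sign between uncalled values was not counted. Without the low-count filter the calls numbered 397 for the genotype effect at stage 5, 285 at stage 6-7, 484 for the genotype effect averaged over stages and 123 in the interaction; at 10 CPM or more in 2 libraries, 88 at stage 6-7 and 157 averaged, with fewer genes tested. DESeq2 called 255 at stage 5 and 57 in the interaction, and limma-voom 3 in the interaction. Off chromosome 3 alone, 36 and 17 genes were called, and against 1.5-fold 25 and 63. Leaving out 1 library gave 66 to 805 calls at stage 5, 89 to 218 at stage 6-7, 174 to 545 averaged and 3 to 296 in the interaction. The stage effects kept counts within 1.5 times under every alternative run. The overlap of calls between stages at an unadjusted p under 0.05 was 76 higher and 163 lower, and off chromosome 3 it was 0 and 11. The rho with the stage effect was -0.136 and -0.127 at stage 5 and 0.298 and 0.266 at stage 6-7 under its other alternatives. With the genotype difference from 1 replicate number and the stage effect from the other it was -0.212 and 0.099 at stage 5 and 0.329 and 0.04 at stage 6-7, and without 1 library -0.316 to 0.042 and -0.026 to 0.272. The odds ratio on chromosome 3 for the 200 genes of smallest p was 1.894 and 6.203. Except where fewer genes or libraries were used, the cause was not tested.

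The replicate numbers do not pair the libraries (their deviations from the group means correlated at -0.06 to 0.04). With the replicate block the counts were 249 at stage 5 and 38 in the interaction, and with a block within stage 340 and 87; those at stage 6-7 (196 and 233) and averaged (345 and 410) stayed within 1.5 times. Of the gene lists, 0 passed with an estimated correlation at stage 5 (4 with the preset one) and 0 at stage 6-7 (1), 3 with the block at stage 6-7, and 3 to 6 and 1 to 5 without 1 library.

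Of the values of named genes, 6 at stage 5, 18 at stage 6-7 and 10 in the interaction lost a call on leaving out a library, and 7, 3 and 8 gained one. Under the other alternatives 7, 13 and 4 lost and 13, 4 and 20 gained one. All 7 at stage 5 and 7 of the 13 at stage 6-7 were lost against 1.5-fold. Depth sets a limit for genes near the floor such as Prat2, and 2 libraries per group limit the rest.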

Other observations

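Of the tests below, those of rises on chromosome 3 and of falls on chromosome 3 that were deeper at stage 6-7 were chosen only after the result was seen, as were the gene groups described.

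Off chromosome 3, 14 genes fell in homozygotes at both stages, of which 4 (tup, peb, Ance and ush) are in the amnioserosa list and 10 are not. Among the 10, the netrin receptor gene fra fell from 319 ± 18.9 to 202 ± 13.99 CPM at stage 5 (log2 -0.66, edgeR adjusted p = 0.00175) and from 306 ± 30.6 to 166 ± 1.45 CPM at stage 6-7 (log2 -0.88, adjusted p = 0.000106). The Cdk inhibitor gene dap fell from 8.84 ± 1.74 to 4.95 ± 0.523 CPM and from 23.3 ± 2.79 to 6.71 ± 0.654 CPM (log2 -0.84 and -1.79, adjusted p = 0.0294 and 2.87e-05). The receptor tyrosine kinase gene Alk (log2 -1.86 and -1.62), Fs (-1.89 and -1.56), kek2 (-1.97 and -1.35) and ana (-1.90 and -1.20) also fell at both stages. The falls of rst, wun2, net and psq ranged from log2 -0.97 to -0.40.

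Called genes with a called neighbour in the same direction within 10 kb made 18 pairs at stage 5 (16 on chromosome 3) and 20 pairs at stage 6-7 (17 on chromosome 3). Every combination within a cluster counts as a pair, overlapping genes are included, and no expected number was computed. On 3R, CG31313, CG8066, Cys and asRNA:CR44095 rose together at stage 5, with log2 changes of 0.81, 1.48, 2.05 and 1.58, and nAChRbeta2, DZIP1 and Jhbp12 at stage 6-7, with 1.12, 1.16 and 1.53. Cys is near the floor (0.328 ± 0.111 to 1.34 ± 0.690 CPM) and lies inside asRNA:CR44095, so the rises of these genes cannot be told apart. Off chromosome 3, egr, CG2269 and sut4 on 2R fell at stage 6-7 (log2 -2.67, -2.25 and -2.29, edgeR adjusted p = 0.0249, 0.0384 and 0.0473), with sut4 inside CG2269. Both were low, at 2.28 to 0.475 CPM for CG2269 and 0.563 to 0.115 CPM for sut4.

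Rises on chromosome 3 may come from genes that are inactive on TM3. Equal output of each zen[7] copy would then allow at most 2-fold, if no heterozygous pool held embryos with TM3 in both copies. A lacZ band alone does not tell such embryos apart, and they would raise this bound. At stage 5, with called rises within 10 kb counted as 1 locus, 18.8% of 16 loci (exact interval 4 to 45.6) held a rise beyond 2-fold by more than 2 standard errors, among them those of Ac78C, CG8066 and nAChRbeta2. At stage 6-7 it was 4.8% of 42 loci (0.6 to 16.2), and the explanation stays open at both stages. The criterion was changed 2 times after a result was seen: any single rise beyond 2-fold would have excluded the explanation at both stages, and a share of genes (5 of 22 at stage 5) against 5% would have excluded it at stage 5.

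Homozygotes come from heterozygous mothers, whose RNA for genes on TM3 may still be present at stage 5, which would make falls on chromosome 3 deeper at stage 6-7. Among genes called lower with the stages averaged, the median interaction was -0.219 for 139 genes on chromosome 3 and 0.118 for 56 off it, a difference of -0.337 (bootstrap interval -0.635 to -0.063, 10000 draws). The interval covers the choice of genes and not noise between libraries, and without 1 library the difference ran from -0.523 to -0.133, with an upper bound of 0.006 without homozygous stage 5 replicate 1. A first criterion, without leaving out libraries, was met by the interval of all libraries, and with the changed one this explanation stays open. Maternal RNA was not measured here, and zen effects that differ with stage stay open.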
